A study of Mus musculus with 29 samples.

How the data were processed

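RNA was counted in 29 libraries of primary mouse cardiac fibroblasts in 10 groups: fresh young and fresh aged cells, and young or aged cells after 48 h on 4 substrates. Libraries were made from 20 ng of RNA with a NEBNext single cell and low input kit, per the labels' protocols. Reads were aligned with STAR 2.7.8a to mm39, per the submitters' processing notes, and the authors deposited raw counts per gene for 55357 Ensembl genes in 29 columns, of which all were tied to a sample. The file name points to HTSeq as the counting tool, and its version, the annotation release and the strand setting are not given in the sources used here. Totals ran from 1192668 to 3275089 counts per library, so that a gene at 10 CPM rested on 12 to 33 counts per library. 1362 genes have no symbol in the table. Sequence of an older build (GRCm38, GENCODE M21) served for GC content only.

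The choices in this and the next 2 paragraphs, and the alternatives except 3, were made before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes of a comparison and calls at an adjusted p under 0.05 without a fold threshold. Fresh cells were fitted alone (6 libraries, 11786 genes), the 23 cultured libraries together in 8 groups (12841 genes), and comparisons of cultured with fresh cells over all 29 libraries (13523 genes). The 14 comparisons were aged over young in fresh cells, StiffA over SoftY, stiff over soft and aged over young ECM within each cell age, the stiffness by ECM interaction within each age, aged over young cultured cells, the interactions of cell age with stiffness and with ECM, and cultured over fresh cells within each age. Means over substrates weigh groups equally. SE values are the absolute log2 fold change over the square root of F. CPM values are counts over TMM-scaled library totals, and log2 CPM used a prior count of 2.

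Gene lists were 40 sets of 800 genes, 792 of them in the table, and were tested with fry of limma 3.58.1 with the same fit, adjusted over the lists of a comparison. They cover contractile genes, fibrillar collagen, collagen processing, basement membrane, matrix proteases, integrins, TGF-beta response, YAP and TAZ targets, resident fibroblast genes, immediate early genes, cytokines and NF-kB targets, interferon-stimulated genes, antigen presentation of class I and class II, complement, senescence, proliferation, cholesterol biosynthesis, glycolysis, hypoxia, respiratory chain genes of the nucleus and of the mitochondrial genome, ribosomal proteins, the unfolded protein response, heat shock, oxidative stress, lysosome and autophagy, growth factors, chondro-osteogenic and adipogenic genes, and sex-linked transcripts. Others hold markers of myeloid cells, neutrophils, lymphocytes, endothelial cells, pericytes, cardiomyocytes, Schwann cells, epicardial cells and erythroid cells. A gene counts in every list that holds it. Genes changed in fresh ageing were tested in culture in the same way.

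Genes were named by a rule. Among genes with an adjusted p under 0.05 and a mean of at least 10 CPM over the libraries compared, the 8 largest log2 folds in each direction were taken. For comparisons of 2 groups every library of 1 group had to lie above every library of the other, and for means over substrates the change had to have 1 sign in every pair of groups averaged. Genes without a symbol, with provisional names (Gm, Rik, LOC) and pseudogenes were left out. From each list with a fry call or at least 3 changed members, up to 4 changed members with the smallest p were taken, and from a list with none changed at most 2 members with the highest mean CPM, as values. Acta2, Postn, Col1a1, Ccn2, Cdkn1a, Cdkn2a, Il6 and Pdgfra were taken in every comparison. Interactions used only the largest folds. A few genes that the rule names are not reported here. Where a group had 0 counts, a lower bound was computed with a floor of 3 counts over the group, and with 1 to 3 counts the ratio of CPM is given with its exact counting interval.

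The fits were tested on simulated data with 200 genes changed by 1.5, 2 and 4-fold. These genes had a mean of at least 10 CPM, and counts were drawn independently for each gene and library. Weaker genes and deviations shared between genes of a library were thus left out, and recovery in the real data may be lower. In fresh cells 62.7%, 85.1% and 100% were recovered among 11499 genes, with 14 false calls in 179. For StiffA over SoftY the shares were 28.4%, 62.7% and 98.5% in young cells (12559 genes) and 25.4%, 74.6% and 97.0% in aged cells (12583 genes), and for stiffness in aged cells 59.7%, 94.0% and 100% (12545 genes). For cultured age they were 79.1%, 98.5% and 100% (12583 genes), and for young cultured over fresh cells 55.2%, 97.0% and 100% (12974 genes). Of the calls, 7.4%, 7.1%, 6.6%, 2.6% and 5.1% were false in these further comparisons, in the order given. A list raised in simulated data was found, and 0 of 37 others were called by fry, in data without correlation between members.

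Alternatives were DESeq2 1.42.0, RLE factors, no filter beyond genes at 0, limma-voom with sample quality weights, the replicate number as a block (in 2 versions), all libraries in 1 fit or those of 1 age, each library left out in turn, camera with a preset correlation of 0.01 or an estimated one, and the 200 top genes of fresh ageing. 3 alternatives were chosen after seeing the data: counts summed per library number for cultured age, the score of each library on an axis of shared deviations as a covariate, and the fit without replicate 3 of young cells on SoftA and on StiffA, which lay farthest below their group means on that axis. The axis is the first principal component of the deviations of log2 CPM from group means, over genes with a mean above 20 CPM. No library was left out of the reported fits, and no pair of libraries was as close as sampling noise alone would make it.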

Results

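Gene expression was counted in 29 RNA-seq libraries of primary mouse cardiac fibroblasts, the cells that lay down the collagen matrix of the heart. 6 libraries came from freshly isolated cells, 3 of young and 3 of aged mice. The other 23 came from cells cultured for 48 h on DECIPHER substrates, scaffolds that hold heart extracellular matrix (ECM) within a hydrogel. The 4 substrates paired matrix of young (Y) or aged (A) heart with a soft or stiff gel, and are called SoftY, StiffY, SoftA and StiffA. Each of the 8 cultured groups had 3 libraries, except young cells on SoftY with 2. Totals ran from 1192668 to 3275089 counts per library. The labels call the libraries of a group biological replicates and do not tie them to animals, so that p-values measure the spread between these libraries. Levels are means of counts scaled by library total (CPM) ± SD. Changes are log2 fold changes ± SE with adjusted p-values of edgeR's quasi-likelihood test, and "rose" and "fell" refer to an adjusted p under 0.05. For each gene list fixed beforehand, limma's fry tested whether its members moved, on balance, in 1 direction, which compares them with no other genes. Counts adjusted over the list alone give genes higher, then lower. Where a called list has no p with an estimated correlation beside it, its call held with one. Strand was not given for the counting in the sources used here, so that the antisense gene Peak1os is uncertain. The same holds for near-identical copies such as Ifit3 and Ifit3b, Serpina3f and Serpina3g, C1s1 and the class I H2 genes. Coordinates are of build mm39.

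Freshly isolated cells of aged and young mice were compared to ask what cardiac ageing changes in these cells before culture. Transcripts of the fibrillar matrix were far lower in aged cells. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94827050 to 94843869), measured 1327 ± 77.8 CPM in young and 257 ± 12.2 CPM in aged cells (n = 3 each), a log2 fold change of -2.40 ± 0.06, adjusted p = 1.69e-12. Col1a2 changed by -2.22 ± 0.08, Col3a1 by -1.56 ± 0.06, elastin (Eln) by -4.18 ± 0.43 and Postn, which encodes the matricellular protein periostin, by -2.51 ± 0.49. 15 of 22 measured members of the fibrillar collagen and fibrotic matrix list fell and 2 rose, among them tenascin C (Tnc) at 1.31 ± 0.05 (3 and 16 adjusted over the list alone, fry adjusted p = 1.92e-04, adjusted p = 0.0698 with an estimated correlation). The list's median stayed the same with Col11a1, which had 0 counts in fresh aged and 41 in fresh young cells, set to its lower bound. Of the genes that process and crosslink collagen, 5 of 16 fell, among them Loxl1 (-0.68 ± 0.05) and Pcolce (-0.75 ± 0.07), and 2 rose (2 and 5 adjusted over the list alone, fry adjusted p = 0.00884, adjusted p = 0.271 with an estimated correlation). Cell cycle genes fell as a block: 30 of 30 proliferation genes were lower, with a median of -1.67, led by the mitotic kinase Plk1 (ENSMUSG00000030867, chromosome 7, 121758662 to 121769097), at 269.8 ± 16.2 CPM in young and 68.4 ± 7.45 CPM in aged cells (-2.01 ± 0.09, adjusted p = 1.12e-09). Cyclin B1 (Ccnb1) changed by -1.84 ± 0.09 (0 and 30 adjusted over the list alone, fry adjusted p = 3.62e-05).

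Genes of inflammation, oxidative stress and matrix breakdown were higher in fresh aged cells. The collagenase gene Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283332) measured 68.6 ± 2.36 CPM in young and 2580.3 ± 41.1 CPM in aged cells (5.20 ± 0.06, adjusted p = 1.39e-16), and the stromelysins Mmp10 and Mmp3 rose by 5.20 ± 0.08 and 1.55 ± 0.03. 11 of 20 matrix proteases and inhibitors rose and 4 fell (11 and 5 adjusted over the list alone, fry adjusted p = 8.28e-05, adjusted p = 0.0534 with an estimated correlation). Among cytokines and NF-kB targets 20 of 29 rose and 3 fell, with the cyclooxygenase gene Ptgs2 at 4.11 ± 0.10, Lif at 2.65 ± 0.10 and the chemokine Cxcl1 at 2.21 ± 0.04 (21 and 3 adjusted over the list alone, fry adjusted p = 6.76e-05). Il6 rose by 0.26 ± 0.10, adjusted p = 0.0479. In the oxidative stress list, 17 of 20 rose and 1 fell, with the cystine transporter Slc7a11 at 3.19 ± 0.07 and heme oxygenase (Hmox1) at 2.90 ± 0.07 (17 and 2 adjusted over the list alone, fry adjusted p = 4.10e-05). 18 of 23 immediate early genes, which answer acute stimuli, rose and 0 fell, with Nr4a1 at 2.53 ± 0.11 and Egr1 at 1.88 ± 0.06 (18 and 0 adjusted over the list alone, fry adjusted p = 7.18e-05). Markers of other cells moved with these groups: 8 of 12 macrophage and myeloid markers rose, among them Cd14 (1.86 ± 0.12) and Cd68 (1.06 ± 0.11, 9 and 0 adjusted over the list alone, fry adjusted p = 6.21e-04, adjusted p = 0.102 with an estimated correlation). So did all 5 measured neutrophil markers, with S100a8 at 3.93 ± 0.53 (5 and 0 adjusted over the list alone, fry adjusted p = 2.96e-04, adjusted p = 0.102 with an estimated correlation). S100a8 itself measured only 9.77 ± 2.00 CPM in aged cells.

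**Figure D1:**
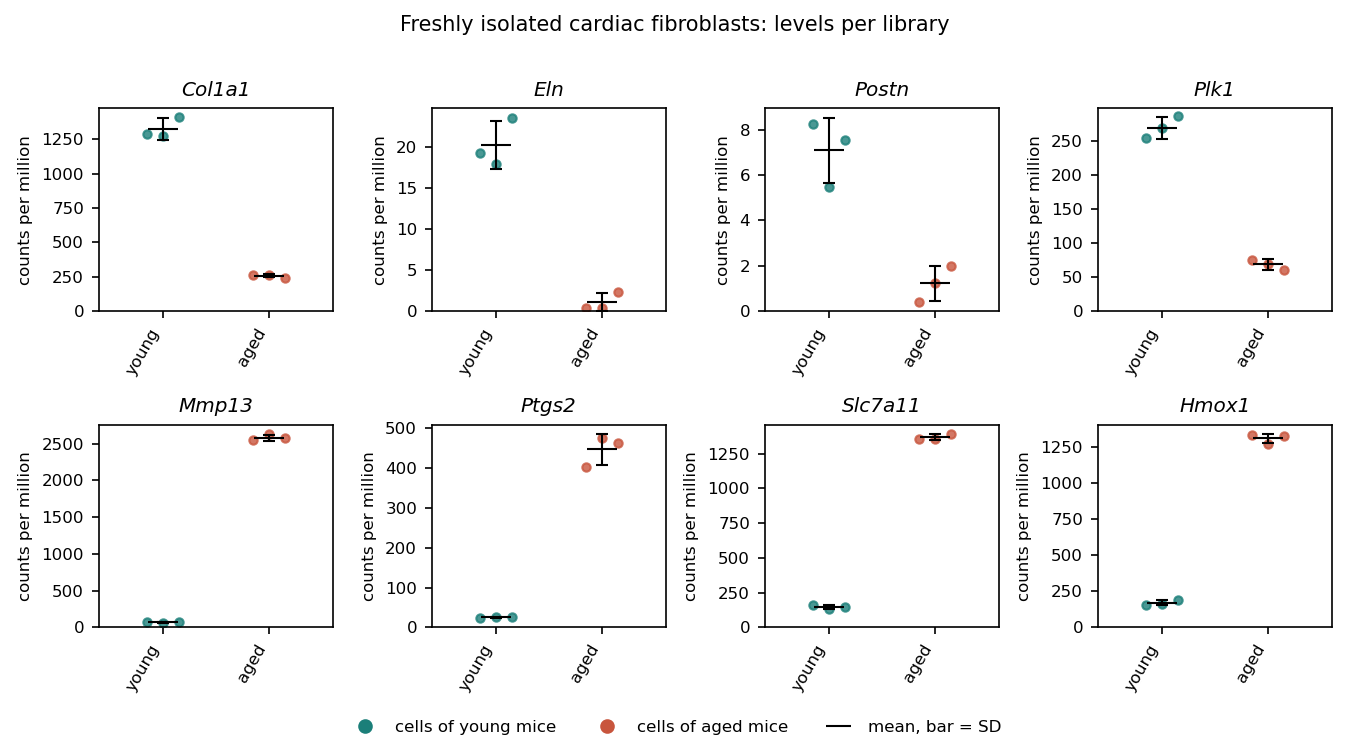
CPM of 8 genes in the 3 fresh libraries of young and the 3 of aged cells. Points are libraries, and bars are the mean ± SD. Col1a1, Eln, Postn and Plk1 were lower in aged cells, and Mmp13, Ptgs2, Slc7a11 and Hmox1 were higher.

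Several further lists were called in fresh aged cells. Lysosome and autophagy genes rose in 16 of 24 cases with 1 lower, among them the autophagy receptor Sqstm1 (1.16 ± 0.06, 17 and 1 adjusted over the list alone, fry adjusted p = 3.39e-04, adjusted p = 0.0828 with an estimated correlation). Among interferon-stimulated genes 16 of 29 rose and 1 fell, with Usp18 at 1.01 ± 0.08 (18 and 1 adjusted over the list alone, fry adjusted p = 1.13e-04, adjusted p = 0.0699 with an estimated correlation). Class I antigen presentation had 8 of 17 higher and 1 lower, with B2m at 0.88 ± 0.06 (10 and 1 adjusted over the list alone, fry adjusted p = 9.48e-04, adjusted p = 0.179 with an estimated correlation). Class II had 5 of 6 higher, with Cd74 at 2.09 ± 0.21 (5 and 0 adjusted over the list alone, fry adjusted p = 7.18e-05, adjusted p = 0.0698 with an estimated correlation). The TGF-beta response list had 10 of 20 higher and 4 lower (12 and 4 adjusted over the list alone, fry adjusted p = 9.42e-05, adjusted p = 0.101 with an estimated correlation). Among targets of the mechanosensitive factors YAP and TAZ, 7 of 19 rose, such as Ankrd1 (1.66 ± 0.05), and 5 fell, such as Amotl2 (-0.78 ± 0.08, 9 and 6 adjusted over the list alone, fry adjusted p = 4.94e-05, adjusted p = 0.0698 with an estimated correlation). The connective tissue growth factor gene Ccn2 rose by 1.34 ± 0.22. Senescence and arrest genes had 8 of 17 higher and 5 lower, with the cell cycle inhibitor Cdkn1a at 1.16 ± 0.08 (9 and 5 adjusted over the list alone, fry adjusted p = 6.21e-04, adjusted p = 0.101 with an estimated correlation). 7 of 14 contractile genes rose and 1 fell (7 and 1 adjusted over the list alone, fry adjusted p = 7.55e-04, adjusted p = 0.182 with an estimated correlation). The myofibroblast marker Acta2 passed no test (0.07 ± 0.20, adjusted p = 0.828). Resident fibroblast genes were split, with 7 of 21 higher, such as decorin (Dcn, 0.48 ± 0.04), and 9 lower, such as Fbln1 (-1.66 ± 0.13) and Pdgfra (-0.26 ± 0.06, 7 and 10 adjusted over the list alone, fry adjusted p = 0.00463, adjusted p = 0.445 with an estimated correlation).

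Further markers of other cells moved in fresh aged cells. Pericyte and smooth muscle markers fell in 3 of 5 cases and rose in 1, with Steap4 at -2.33 ± 0.20 and Ndufa4l2 at 1.06 ± 0.19 (1 and 3 adjusted over the list alone, fry adjusted p = 0.00108, adjusted p = 0.153 with an estimated correlation). Schwann cell markers rose in 2 of 3 cases, with Prnp at 0.75 ± 0.14 (2 and 0 adjusted over the list alone, fry adjusted p = 6.21e-04, adjusted p = 0.371 with an estimated correlation). Endothelial markers rose in 3 of 12 cases, with Cdh5 at 0.95 ± 0.14 (3 and 0 adjusted over the list alone, fry adjusted p = 0.0166, adjusted p = 0.371 with an estimated correlation). 1 of 2 epicardial markers fell, Tbx18 at -0.82 ± 0.24 (0 and 1 adjusted over the list alone, fry adjusted p = 0.0366, adjusted p = 0.690 with an estimated correlation), and the 1 cardiomyocyte marker measured, Myl4, was called by its list test alone (0 and 1 adjusted over the list alone, fry adjusted p = 0.0304, adjusted p = 0.639 with an estimated correlation).

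Across all genes, 1771 rose and 1979 fell of 11786 tested in fresh cells, 494 and 672 of them by more than 2-fold. The largest rises by the fixed rule included Nefm, a neurofilament gene with 2 counts in young and 195 in aged cells (ratio 113, exact 95% counting interval 30.8 to 938), Arg2 (4.41 ± 0.27) and the cholesterol carrier gene Star (3.94 ± 0.15). The largest falls included the amino acid transporter gene Slc38a4 (-4.29 ± 0.21), Spon2 (-4.05 ± 0.10) and Ccn5 (-3.66 ± 0.26). Floors of 3 counts and counting intervals here cover counting error only. All 6 fresh libraries shared 1 letter in their names, while numbers 1 to 3 were young and 4 to 6 aged, so that a preparation that follows the number cannot be separated from age. Of 99 genes at the low end of an axis along which libraries of a group differed, 42 rose and 10 fell in fresh aged cells, with a median of 0.32.

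Culture was compared with fresh isolation within each age to ask what 48 h on the substrates did to the cells. Fresh and cultured libraries had different letters in their names. A preparation that follows the letter thus cannot be told apart from culture in these comparisons. Matrix and contractile genes were far higher after culture. Acta2 (ENSMUSG00000035783, chromosome 19, 34218490 to 34232991), which encodes smooth muscle actin, rose by 5.75 ± 0.15 in young and 5.33 ± 0.15 in aged cells, from 21.0 ± 1.79 CPM fresh to 1284 ± 64.1 CPM in young cells on StiffY. Col1a1 rose by 3.23 ± 0.07 and 5.35 ± 0.08. In the fibrillar collagen list, 21 of 25 rose and 2 fell at both ages (young: 21 and 2 adjusted over the list alone, fry adjusted p = 4.87e-21). In aged cells the list gave 21 and 3 adjusted over the list alone, fry adjusted p = 2.68e-22. Contractile genes rose in 16 of 17 cases in young and 13 of 17 in aged cells, with 1 and 4 lower (young: 16 and 1 adjusted over the list alone, fry adjusted p = 3.59e-18). Aged cells gave 13 and 4 adjusted over the list alone, fry adjusted p = 1.40e-15 for it. Cnn1, an actin-binding contractile gene, had 0 counts in fresh young cells and was at least 47.4-fold higher in culture, and Col11a1, at 0 in fresh aged cells, at least 502-fold. Cholesterol biosynthesis genes rose in 22 of 23 cases with 1 lower at both ages, with Hmgcs1 at 2.17 ± 0.10 and 2.17 ± 0.10 (young: 22 and 1 adjusted over the list alone, fry adjusted p = 2.66e-18). Aged cells gave 22 and 1 adjusted over the list alone, fry adjusted p = 4.76e-18 for it.

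Inflammatory and interferon genes were lower after culture. 25 of 30 cytokines and NF-kB targets fell in young and 26 of 30 in aged cells, with 2 and 3 higher, and the chemokine Ccl2 changed by -3.08 ± 0.04 and -4.67 ± 0.04 (young: 2 and 25 adjusted over the list alone, fry adjusted p = 4.23e-17). In aged cells the list gave 4 and 26 adjusted over the list alone, fry adjusted p = 2.68e-22. Interferon-stimulated genes fell in 27 and 26 of 29 cases, with 0 and 1 higher (young: 0 and 28 adjusted over the list alone, fry adjusted p = 7.23e-13). Its result in aged cells was 1 and 26 adjusted over the list alone, fry adjusted p = 2.69e-15. Beside these groups, 10 of 12 myeloid markers fell in young and all 12 in aged cells, with Cd68 at -3.45 ± 0.18 and -5.62 ± 0.18 (young: 0 and 12 adjusted over the list alone, fry adjusted p = 8.14e-16). In aged cells the list gave 0 and 12 adjusted over the list alone, fry adjusted p = 1.68e-19. The 5 neutrophil markers fell at both ages (young: 0 and 5 adjusted over the list alone, fry adjusted p = 1.48e-14, adjusted p = 0.0917 with an estimated correlation). Aged cells gave 0 and 5 adjusted over the list alone, fry adjusted p = 4.89e-19. Proliferation genes fell in 30 of 30 cases in young cells (0 and 30 adjusted over the list alone, fry adjusted p = 2.41e-21). In aged cells 14 of 30 rose and 9 fell, with a positive median and a negative mean (14 and 9 adjusted over the list alone, fry adjusted p = 6.21e-05, adjusted p = 0.729 with an estimated correlation). Immediate early genes moved apart by age: 13 of 24 rose and 5 fell in young cells (13 and 5 adjusted over the list alone, fry adjusted p = 3.89e-12). In aged cells 1 rose and 22 fell (1 and 22 adjusted over the list alone, fry adjusted p = 1.87e-21). Nr4a1 changed by 2.99 ± 0.14 in young and -4.36 ± 0.12 in aged cells. Whether these lists differed between ages in their response to culture was not tested. Over all 13523 genes tested, 3659 rose and 4040 fell in young cells, and 4042 rose and 4392 fell in aged cells. The growth factor gene Csf3 had the largest fall by the rule in young cells (-10.34 ± 0.18), and in aged cells, with 1 count in culture, its fresh to cultured ratio was 56306 (interval 10104 to 2224124).

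Markers of other cells also moved with the contractile rise. Pericyte and smooth muscle markers rose in 6 of 8 cases at both ages, with 1 lower in young and 0 in aged cells, among them Ndufa4l2 in young (1.10 ± 0.17, 6 and 1 adjusted over the list alone, fry adjusted p = 1.05e-09, adjusted p = 0.113 with an estimated correlation) and Pdgfrb in aged cells (1.52 ± 0.10, 6 and 0 adjusted over the list alone, fry adjusted p = 6.10e-14). Schwann cell markers rose in 3 of 3 cases in young (3 and 0 adjusted over the list alone, fry adjusted p = 2.84e-14) and 2 of 3 in aged cells (2 and 0 adjusted over the list alone, fry adjusted p = 4.87e-13, adjusted p = 0.0656 with an estimated correlation), with Prnp at 2.75 ± 0.14 and 2.45 ± 0.14. Both measured cardiomyocyte markers, Myl4 and Tnnt2, rose at each age (young: 2 and 0 adjusted over the list alone, fry adjusted p = 7.12e-10, adjusted p = 0.132 with an estimated correlation). The aged result was 2 and 0 adjusted over the list alone, fry adjusted p = 1.51e-08, adjusted p = 0.355 with an estimated correlation. Epicardial markers had 1 of 3 higher and 1 lower in young (1 and 1 adjusted over the list alone, fry adjusted p = 7.66e-04, adjusted p = 0.604 with an estimated correlation), and 2 higher and 1 lower in aged cells (2 and 1 adjusted over the list alone, fry adjusted p = 1.64e-05, adjusted p = 0.493 with an estimated correlation), with Aldh1a2 falling at both ages (-0.51 ± 0.08 and -0.52 ± 0.08). Endothelial markers fell in 10 of 14 cases in young cells, with 3 higher (3 and 10 adjusted over the list alone, fry adjusted p = 2.57e-06, adjusted p = 0.431 with an estimated correlation), and in 8 of 14 in aged cells, with 4 higher (4 and 8 adjusted over the list alone, fry adjusted p = 1.13e-04, adjusted p = 0.718 with an estimated correlation), with Cdh5 at -1.72 ± 0.16 and -1.28 ± 0.14. Of 100 genes at the high end of an axis along which libraries of a group differed, 44 fell and 7 rose with culture in aged cells.

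**Figure D2:**
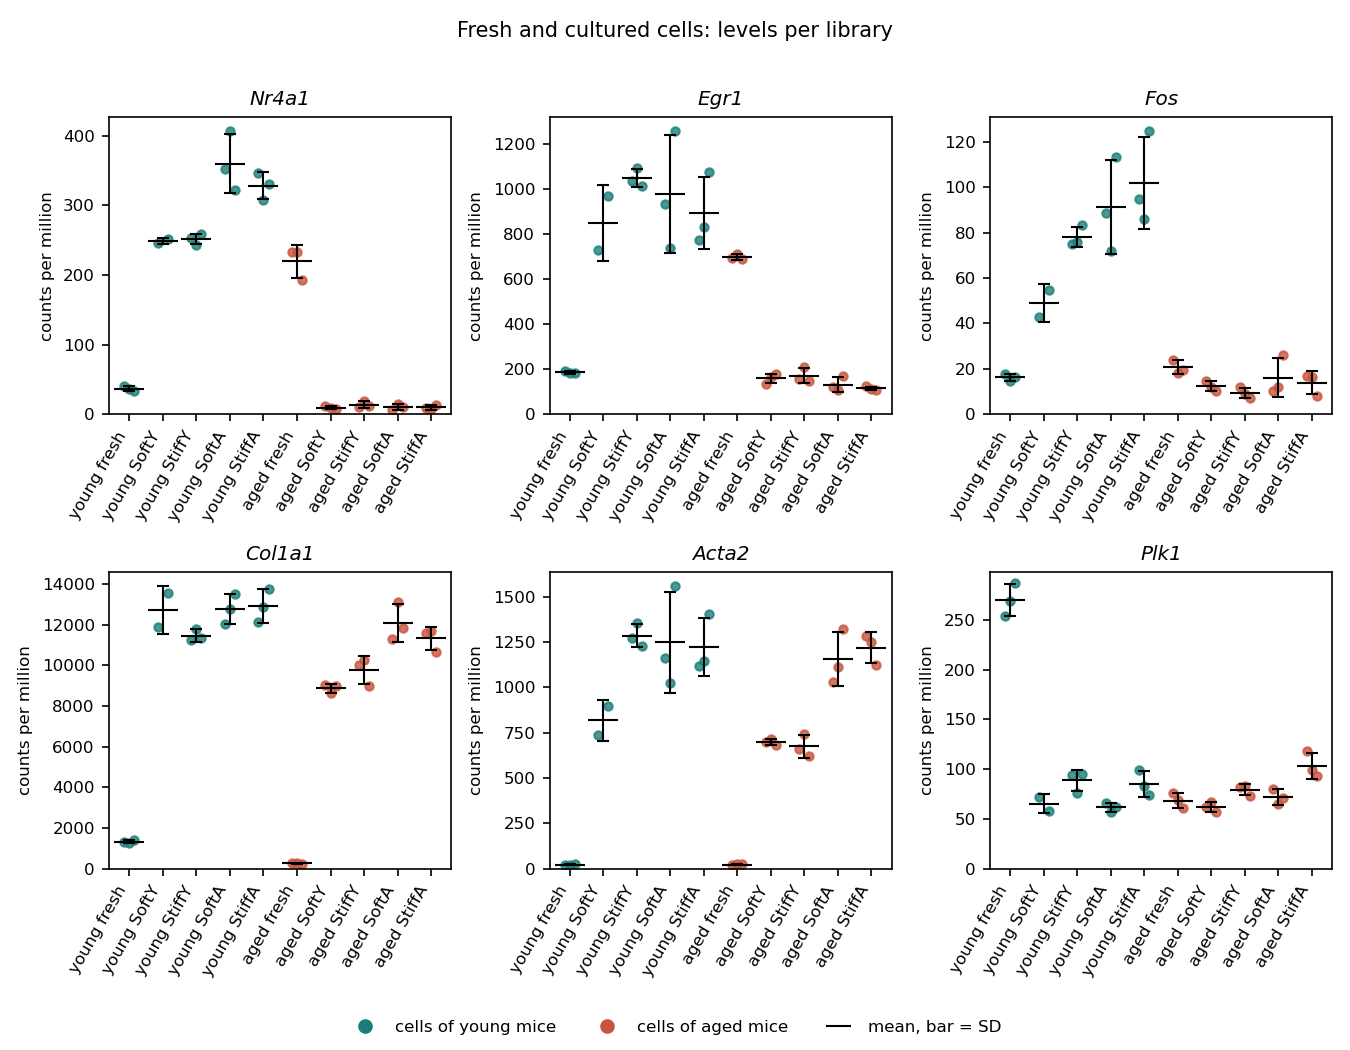
CPM of 6 genes in the 10 groups of fresh and cultured cells. Points are libraries, and bars are the mean ± SD. Nr4a1 was higher in fresh aged than in fresh young cells and lower in cultured aged than in cultured young cells, and Col1a1 and Acta2 were higher in every cultured group than in fresh cells.

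StiffA and SoftY, the substrates that pair both aged cues and both young cues, were compared to ask how cells respond when matrix and stiffness age together. In young cells the matrix response was selective. Timp3, an inhibitor of matrix proteases (ENSMUSG00000020044, chromosome 10, 86136236 to 86185371), rose by 1.51 ± 0.12, adjusted p = 5.77e-09, from 688 ± 95.9 CPM (n = 2) to 1962 ± 290.2 CPM (n = 3). Col12a1 rose by 1.66 ± 0.11 and the crosslinking enzyme gene Lox by 1.07 ± 0.15, while the basement membrane collagen Col15a1 changed by -2.63 ± 0.18, Col6a3 by -1.71 ± 0.22 and Col1a1 by 0.02 ± 0.08, adjusted p = 0.930. The fibrillar collagen list had 7 of 25 higher and 4 lower (7 and 5 adjusted over the list alone, fry adjusted p = 0.0695, with its median and mean of opposite sign). Collagen processing had 5 of 17 higher (6 and 1 adjusted over the list alone, fry adjusted p = 2.62e-04). 8 of 16 contractile genes rose, with Acta2 at 0.58 ± 0.14 (9 and 0 adjusted over the list alone, fry adjusted p = 1.14e-05). So did 6 of 19 YAP and TAZ targets, with Ankrd1 at 0.82 ± 0.12 (9 and 0 adjusted over the list alone, fry adjusted p = 7.50e-06). Cholesterol biosynthesis rose in 13 of 23 cases (16 and 0 adjusted over the list alone, fry adjusted p = 1.64e-07). Glycolysis rose in 7 of 16, with the pyruvate kinase gene Pkm at 0.65 ± 0.08 (11 and 0 adjusted over the list alone, fry adjusted p = 4.71e-05). Complement genes fell in 7 of 12 cases, with C3 at -0.82 ± 0.09 (1 and 8 adjusted over the list alone, fry adjusted p = 9.02e-07). Cytokines and NF-kB targets fell in 11 of 24 cases, with 2 higher, led by the acute-phase gene Saa3 (-3.10 ± 0.38) and Ccl2 (-1.20 ± 0.08, 3 and 13 adjusted over the list alone, fry adjusted p = 4.71e-05). Beside them the myeloid marker Lyz2 changed by -0.96 ± 0.28 (0 and 2 adjusted over the list alone, fry adjusted p = 0.0196, adjusted p = 0.249 with an estimated correlation), the pericyte marker Steap4 by -1.93 ± 0.14 (0 and 3 adjusted over the list alone, fry adjusted p = 4.71e-05) and the Schwann cell marker Gpm6b by -0.55 ± 0.09 (0 and 1 adjusted over the list alone, fry adjusted p = 0.0116, adjusted p = 0.202 with an estimated correlation). 9 of 25 resident fibroblast genes fell and 3 rose, with Pdgfra at -0.83 ± 0.10 (4 and 11 adjusted over the list alone, fry adjusted p = 4.71e-05). The lipid carrier gene Apoe changed by -1.60 ± 0.10, and Cdkn1a rose by 0.82 ± 0.12.

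In aged cells the same contrast raised 10 of 30 proliferation genes, with Plk1 at 0.76 ± 0.13 (17 and 0 adjusted over the list alone, fry adjusted p = 2.70e-07). Contractile genes rose in 8 of 16 cases, with Acta2 at 0.82 ± 0.12 (13 and 0 adjusted over the list alone, fry adjusted p = 2.11e-06). Cholesterol biosynthesis rose in 12 of 23 cases (17 and 0 adjusted over the list alone, fry adjusted p = 2.70e-07). Glycolysis rose in 7 of 16 (10 and 0 adjusted over the list alone, fry adjusted p = 2.01e-05). Timp3 rose by 1.30 ± 0.11, the crosslinking transglutaminase gene Tgm2 by 1.38 ± 0.16, Lox by 1.03 ± 0.13 and Col1a1 by 0.36 ± 0.07, and Apoe changed by -1.69 ± 0.10. 16 of 29 interferon-stimulated genes fell and 0 rose, with Ifit1 at -2.09 ± 0.20 (0 and 18 adjusted over the list alone, fry adjusted p = 7.44e-05). 6 of 12 complement genes fell (0 and 6 adjusted over the list alone, fry adjusted p = 1.22e-05). 4 of 13 endothelial markers rose beside the contractile genes, with Tie1 at 2.12 ± 0.42 and Pecam1 at 1.45 ± 0.34 (5 and 0 adjusted over the list alone, fry adjusted p = 9.27e-05). The Schwann cell marker Gpm6b changed by -0.44 ± 0.08 (0 and 1 adjusted over the list alone, fry adjusted p = 0.00548, adjusted p = 0.129 with an estimated correlation). Of the 100 high-end genes of the axis of library differences, 1 fell and 0 rose, and their median was -0.78.

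In all, 384 genes rose and 292 fell in young cells, and 288 rose and 253 fell in aged cells, of 12841 tested. 163 genes rose at both ages, against 8.61 if the lists were independent, and 135 fell at both, against 5.75, while 1 moved in opposite directions (the libraries of both comparisons are separate). Each substrate had 1 letter in its library names at both ages. A shift of a letter would thus be shared by both ages, and it cannot be told apart from the substrate. Both comparisons also came from 1 fit. The young count of 676 fell without either replicate of young cells on SoftY. The aged count of 541 was 318, 350 and 302 without replicates 1, 2 and 3 of aged cells on SoftY, 280 and 298 without replicates 1 and 2 on StiffA, and 1099 with limma-voom sample weights.

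**Figure D3:**
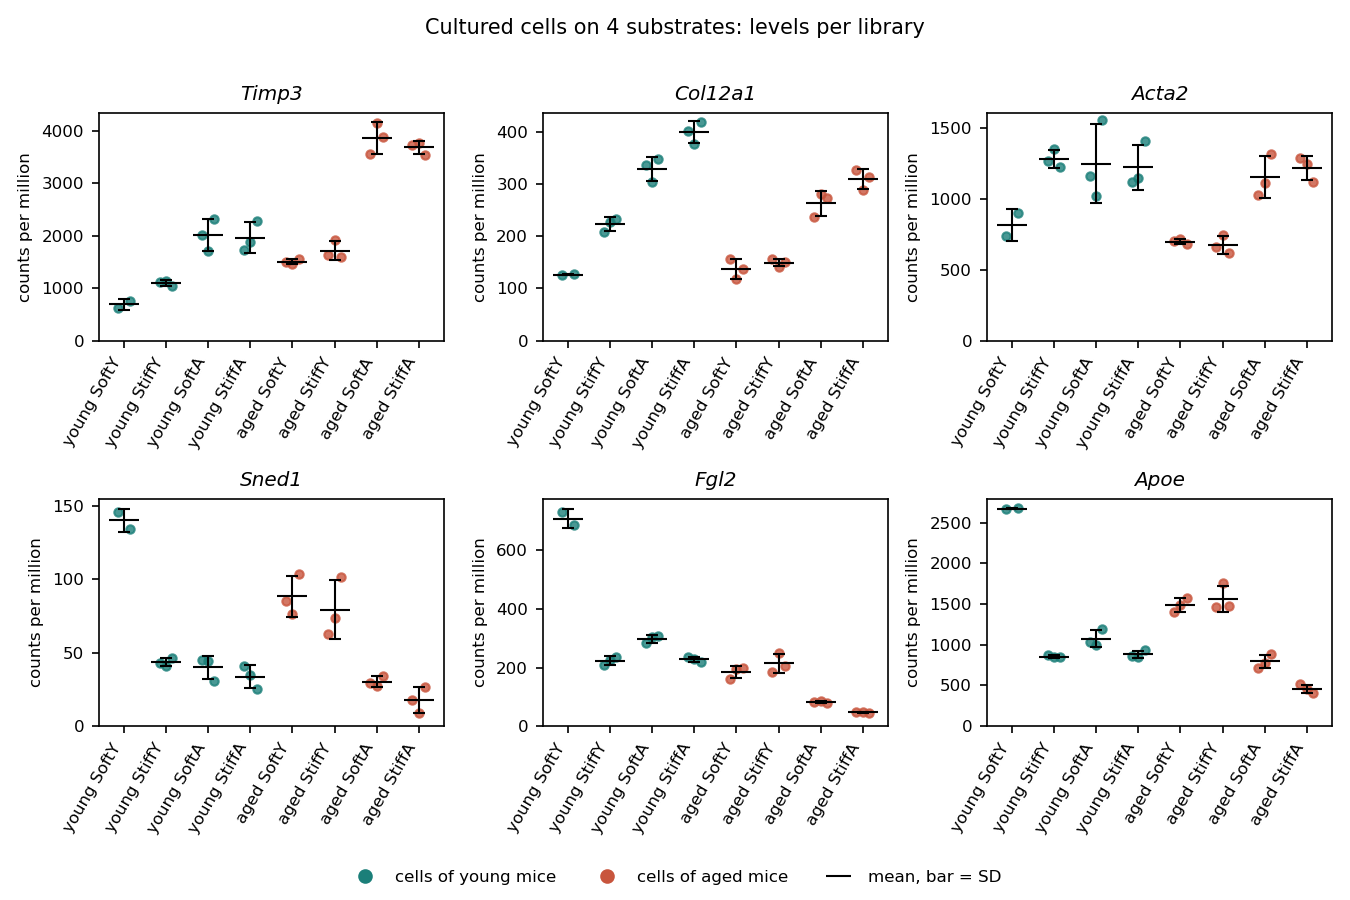
CPM of 6 genes in the 8 cultured groups. Points are libraries, and bars are the mean ± SD. Timp3 and Col12a1 were higher on substrates with aged ECM than on those with young ECM, and Sned1, Fgl2 and Apoe were lower on StiffA than on SoftY at both ages.

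Stiff and soft substrates were compared, averaged over both matrices, to separate the mechanical cue. In young cells interferon-stimulated genes rose: 15 of 29 were higher and 0 lower, with Ifit1, an antiviral gene (ENSMUSG00000034459, chromosome 19, 34618271 to 34627410), at 1.33 ± 0.15, adjusted p = 3.01e-06 and Isg15 at 1.24 ± 0.19 (24 and 0 adjusted over the list alone, fry adjusted p = 1.29e-04). Proliferation genes rose in 7 of 30 cases, with Ccnb1 at 0.47 ± 0.09 (21 and 0 adjusted over the list alone, fry adjusted p = 1.80e-07). 4 of 16 contractile genes rose, such as the focal adhesion gene Zyx (0.33 ± 0.06, 12 and 0 adjusted over the list alone, fry adjusted p = 1.39e-05). So did 4 of 19 YAP and TAZ targets, such as Ccn2 (0.47 ± 0.11, 5 and 0 adjusted over the list alone, fry adjusted p = 1.27e-05). 12 of 24 cytokines and NF-kB targets fell and 1 rose, with Ccl2 at -0.88 ± 0.06 and Saa3 at -2.31 ± 0.28 (2 and 13 adjusted over the list alone, fry adjusted p = 1.15e-05). Complement fell in 7 of 12 cases (0 and 7 adjusted over the list alone, fry adjusted p = 2.92e-07). 9 of 25 resident fibroblast genes fell and 1 rose, with Fbln1 at -0.78 ± 0.06 (2 and 11 adjusted over the list alone, fry adjusted p = 2.42e-06). The myeloid marker Lyz2 fell beside them (-0.93 ± 0.20, 0 and 2 adjusted over the list alone, fry adjusted p = 0.00555, adjusted p = 0.0906 with an estimated correlation). Of the endothelial markers Pecam1 fell (-1.46 ± 0.31) and Ptprb rose (0.46 ± 0.12, 1 and 3 adjusted over the list alone, fry adjusted p = 0.00555, adjusted p = 0.0896 with an estimated correlation). Pericyte and smooth muscle markers fell as a list, with Steap4 the 1 of 7 members that passed over all genes (-1.51 ± 0.10, 0 and 3 adjusted over the list alone, fry adjusted p = 5.22e-06). The Schwann cell marker Gpm6b (-0.53 ± 0.06, 0 and 1 adjusted over the list alone, fry adjusted p = 0.00440, adjusted p = 0.0896 with an estimated correlation) and the epicardial marker Aldh1a2 (-0.69 ± 0.08, 0 and 1 adjusted over the list alone, fry adjusted p = 0.0126, adjusted p = 0.158 with an estimated correlation) fell too, and for these 2 lists the median was above 0 and the mean below 0.

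In aged cells stiffness lowered interferon-stimulated genes instead: 18 of 29 fell and 0 rose, with Cmpk2 at -2.56 ± 0.28, Ifit1 at -1.84 ± 0.14, adjusted p = 2.13e-08 and Ifit3b at -1.60 ± 0.16 (0 and 27 adjusted over the list alone, fry adjusted p = 7.23e-06). The test of this difference between ages was called for the list, with 22 of 29 members lower in the interaction and a median of -1.39 (0 and 27 adjusted over the list alone, fry adjusted p = 1.66e-06). Of other genes few passed: Plk1 was the only gene to rise (0.45 ± 0.10), with proliferation called as a list (7 and 0 adjusted over the list alone, fry adjusted p = 8.14e-05). The resident gene Dpt fell (-0.53 ± 0.07, 0 and 7 adjusted over the list alone, fry adjusted p = 0.00293). Acta2 (0.02 ± 0.09, adjusted p = 1) and Col1a1 (0.02 ± 0.05, adjusted p = 0.998) passed no test. Myeloid markers had 0 of 5 changed (0 and 0 adjusted over the list alone, fry adjusted p = 0.778).

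Stiffness changed 213 genes upward and 244 downward in young cells, and 1 and 37 in aged cells. 1 gene rose and 6 fell at both ages, against 0.0166 and 0.703 if independent, and 13 moved in opposite directions. Shifts of library letters, shared by both ages, cannot be told apart from stiffness within an age. The young count of 457 was lower without replicate 1 of young cells on SoftY.

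**Figure D4:**
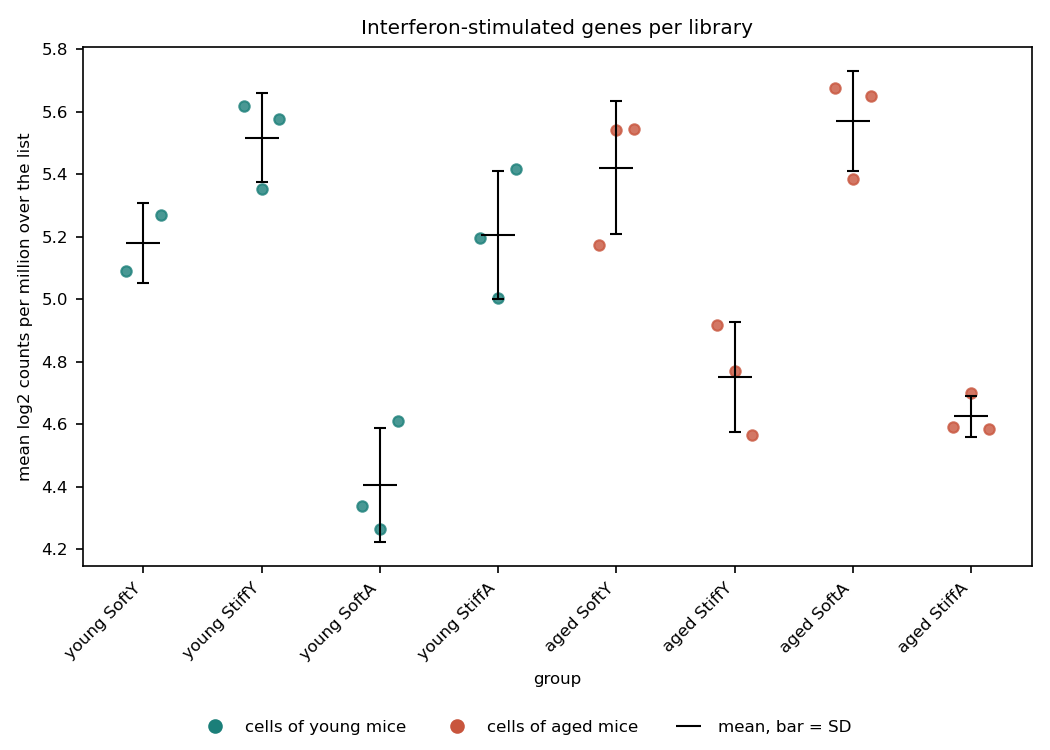
Mean log2 CPM over the interferon-stimulated gene list in each cultured library, with the 8 groups along the axis. The group means run from 4.40 (young cells on SoftA) to 5.57 (aged cells on SoftA), and the largest SD within a group is 0.213.

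Aged and young ECM were compared, averaged over both stiffnesses, to separate the biochemical cue. In young cells cholesterol biosynthesis rose in 10 of 23 cases, with Hmgcs1 at 0.44 ± 0.08 (15 and 0 adjusted over the list alone, fry adjusted p = 1.58e-07). Matrix genes rose with it: Timp3 by 1.19 ± 0.08, adjusted p = 6.81e-10, Col12a1 by 1.11 ± 0.08 and Lox by 0.78 ± 0.10. The fibrillar collagen list had 6 of 25 higher and 2 lower (10 and 3 adjusted over the list alone, fry adjusted p = 2.32e-04). Collagen processing had 4 of 17 higher (6 and 0 adjusted over the list alone, fry adjusted p = 2.32e-04). 4 of 22 immediate early genes rose, with Btg2 at 0.54 ± 0.07 (6 and 0 adjusted over the list alone, fry adjusted p = 2.80e-04). Interferon-stimulated genes fell in 10 of 29 cases, with Oas1a at -0.99 ± 0.16 (0 and 20 adjusted over the list alone, fry adjusted p = 5.12e-04). 2 of 30 proliferation genes fell, Mcm6 (-0.36 ± 0.08) and Tpx2 (-0.39 ± 0.10, 0 and 8 adjusted over the list alone, fry adjusted p = 3.18e-06). The epicardial marker Upk3b rose by 0.87 ± 0.18 (2 and 0 adjusted over the list alone, fry adjusted p = 0.00797, adjusted p = 0.104 with an estimated correlation). Endothelial markers were called upward as a list with 0 of 13 members passing over all genes (0 and 0 adjusted over the list alone, fry adjusted p = 0.0122, adjusted p = 0.104 with an estimated correlation).

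With aged ECM, contractile genes of aged cells rose in 11 of 16 cases, with Acta2 at 0.80 ± 0.09, adjusted p = 6.86e-07 and Cnn1 at 1.56 ± 0.20 (15 and 0 adjusted over the list alone, fry adjusted p = 1.92e-07). The fibrillar collagen list had 11 of 25 higher and 4 lower, with Col12a1 at 1.01 ± 0.07 and Col1a1 at 0.34 ± 0.05 (12 and 4 adjusted over the list alone, fry adjusted p = 4.84e-06). Collagen processing had 7 of 17 higher, with Tgm2 at 1.31 ± 0.11 (8 and 0 adjusted over the list alone, fry adjusted p = 2.99e-07). Timp3 rose by 1.24 ± 0.07. Cholesterol biosynthesis rose in 16 of 23 cases (19 and 0 adjusted over the list alone, fry adjusted p = 5.08e-08). Glycolysis rose in 7 of 16 (12 and 0 adjusted over the list alone, fry adjusted p = 4.84e-06). The unfolded protein response list had 9 of 24 higher (14 and 0 adjusted over the list alone, fry adjusted p = 1.63e-05), and proliferation 5 of 30 (12 and 0 adjusted over the list alone, fry adjusted p = 3.22e-06). 6 of 12 complement genes fell and 1 rose (2 and 7 adjusted over the list alone, fry adjusted p = 5.31e-06). 9 of 25 resident fibroblast genes fell and 4 rose, with Pdgfra at -0.64 ± 0.06 (4 and 11 adjusted over the list alone, fry adjusted p = 1.24e-04). Fgl2, an immunoregulatory gene, changed by -1.67 ± 0.08, Sned1 by -1.87 ± 0.17 and Apoe by -1.33 ± 0.07. 5 of 13 endothelial markers rose beside these groups, with Tie1 at 1.42 ± 0.28 (5 and 0 adjusted over the list alone, fry adjusted p = 4.84e-06). Of the 100 genes at the high end of the axis of library differences, 2 fell with aged ECM and their median was -0.76.

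Aged ECM changed 214 genes upward and 106 downward in young cells, and 532 and 424 in aged cells. 148 genes rose at both ages, against 8.87 if independent, 60 fell at both, against 3.50, and 0 moved in opposite directions. Shifts of library letters would also be shared by both ages and cannot be told apart from the ECM. The young count of 320 was lower without replicate 1 of young cells on SoftY. The aged count of 956 was 596 without replicate 3 of aged cells on StiffY and 1655 with limma-voom sample weights.

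Interaction tests asked whether 1 cue acted differently with the other cue or with cell age. Between ages, stiffness acted differently on 41 genes toward higher and 60 toward lower levels in aged cells. The largest differences by the rule were Saa3 (2.02 ± 0.44) and Cmpk2 (-3.36 ± 0.41), a nucleotide kinase gene induced by interferon. Complement genes (5 and 0 adjusted over the list alone, fry adjusted p = 7.19e-04) and cytokines and NF-kB targets (6 and 1 adjusted over the list alone, fry adjusted p = 0.0143) differed upward, with 4 and 3 members called. So did endothelial (4 and 1 adjusted over the list alone, fry adjusted p = 0.0243, adjusted p = 0.0708 with an estimated correlation) and pericyte markers (2 and 0 adjusted over the list alone, fry adjusted p = 0.00323), with 1 member each, and myeloid markers with 0 (1 and 0 adjusted over the list alone, fry adjusted p = 0.0315, adjusted p = 0.0978 with an estimated correlation). Resident fibroblast genes (4 higher, 7 and 2 adjusted over the list alone, fry adjusted p = 0.0186, adjusted p = 0.0708 with an estimated correlation) and adipogenic genes (3, 3 and 0 adjusted over the list alone, fry adjusted p = 0.0261, adjusted p = 0.0922 with an estimated correlation) differed upward too. Chondro-osteogenic genes (1, 3 and 1 adjusted over the list alone, fry adjusted p = 0.0148) and matrix proteases (0, 2 and 0 adjusted over the list alone, fry adjusted p = 0.0148, adjusted p = 0.0794 with an estimated correlation) did likewise. Downward differed YAP and TAZ targets (1 lower, 0 and 3 adjusted over the list alone, fry adjusted p = 0.00189) and senescence and arrest genes (3 lower and 1 higher, 1 and 6 adjusted over the list alone, fry adjusted p = 0.00282). With 0 members called, contractile (0 and 0 adjusted over the list alone, fry adjusted p = 0.00321) and proliferation genes (0 and 0 adjusted over the list alone, fry adjusted p = 0.00392) did so as lists. Cholesterol biosynthesis (0 and 0 adjusted over the list alone, fry adjusted p = 0.0261, adjusted p = 0.0978 with an estimated correlation) and immediate early genes (0 and 0 adjusted over the list alone, fry adjusted p = 0.0229, adjusted p = 0.0708 with an estimated correlation) also did.

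Aged ECM acted differently between ages on 3 genes upward, among them Oas1a (1.15 ± 0.21), and 9 downward, among them Apoe (-0.69 ± 0.10). This count of 12 was 5, 3, 3, 3, 33 and 5 without replicates 1 and 2 of young cells on SoftY, replicate 3 of aged cells on SoftY, replicates 1 and 3 of young cells on SoftA and replicate 3 of aged cells on SoftA. It was 33 with DESeq2, 33 with limma-voom sample weights and 19 with all libraries in 1 fit. It was 111 both with no filter and without replicate 3 of young cells on SoftA and on StiffA together. Proliferation genes differed as a list (1 member higher and 0 lower, 21 and 0 adjusted over the list alone, fry adjusted p = 1.14e-07), and so did contractile genes (0 and 0, 5 and 0 adjusted over the list alone, fry adjusted p = 0.00359). Interferon-stimulated genes (1 higher, 18 and 0 adjusted over the list alone, fry adjusted p = 0.00863) and collagen processing genes (0, 2 and 0 adjusted over the list alone, fry adjusted p = 0.0426, adjusted p = 0.0958 with an estimated correlation) also differed upward. Resident fibroblast genes differed downward (3 lower, 0 and 7 adjusted over the list alone, fry adjusted p = 0.00863). So did immediate early genes (0, 0 and 1 adjusted over the list alone, fry adjusted p = 0.00863) and TGF-beta response genes (0, 0 and 0 adjusted over the list alone, fry adjusted p = 0.0426, adjusted p = 0.384 with an estimated correlation).

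Stiffness and ECM interacted on 64 genes upward and 15 downward in young cells, led upward by the lysophospholipase gene Enpp2 (4.96 ± 0.28) and Col15a1 (3.76 ± 0.30). The transcription factor gene Tcf21 (-1.15 ± 0.26) was among those downward. The 100 high-end genes of the axis of library differences had a median of 0.39 here, with 0 called. Complement genes differed upward (4 members, 6 and 0 adjusted over the list alone, fry adjusted p = 6.50e-04). Proliferation (0 and 8 adjusted over the list alone, fry adjusted p = 8.88e-06) and cholesterol biosynthesis (0 and 6 adjusted over the list alone, fry adjusted p = 4.43e-04) differed downward, with 1 and 0 members. Pericyte markers differed upward (1 member, 1 and 0 adjusted over the list alone, fry adjusted p = 0.0189, adjusted p = 0.0983 with an estimated correlation). Cardiomyocyte markers differed downward (0 members, 0 and 0 adjusted over the list alone, fry adjusted p = 0.0281, adjusted p = 0.176 with an estimated correlation). Contractile genes (0 members, 0 and 7 adjusted over the list alone, fry adjusted p = 2.27e-04) and YAP and TAZ targets (1, 0 and 4 adjusted over the list alone, fry adjusted p = 0.00808, adjusted p = 0.0809 with an estimated correlation) differed downward. Their changes with stiffness given above are averages over both ECMs. Immediate early (0 and 3 adjusted over the list alone, fry adjusted p = 0.00622) and glycolysis genes (0 and 6 adjusted over the list alone, fry adjusted p = 0.0189, adjusted p = 0.153 with an estimated correlation) did so with 0 members. The same held for hypoxia (0 and 1 adjusted over the list alone, fry adjusted p = 0.0189, adjusted p = 0.176 with an estimated correlation) and nuclear respiratory chain genes (0 and 0 adjusted over the list alone, fry adjusted p = 0.0345, adjusted p = 0.176 with an estimated correlation). Resident fibroblast genes differed upward (6 higher and 1 lower, 7 and 3 adjusted over the list alone, fry adjusted p = 0.00808, adjusted p = 0.0809 with an estimated correlation). Basement membrane genes (2 higher, 2 and 0 adjusted over the list alone, fry adjusted p = 0.0415, adjusted p = 0.244 with an estimated correlation) and matrix proteases (1 and 1, 3 and 2 adjusted over the list alone, fry adjusted p = 0.0485, adjusted p = 0.244 with an estimated correlation) did too. So did adipogenic genes, with a median below 0 and a mean above it (3 higher, 3 and 1 adjusted over the list alone, fry adjusted p = 0.0350, adjusted p = 0.176 with an estimated correlation).

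The count of 79 was 47 without replicate 1 of young cells on SoftY, 51, 52 and 52 without replicates 1, 2 and 3 on StiffY, and 47 and 211 without replicates 1 and 2 on SoftA. It was 152 with DESeq2, 152 with limma-voom sample weights, 145 with all libraries in 1 fit and 186 with no filter. In aged cells 0 genes differed upward and 3 downward, Htra3 (-1.31 ± 0.21), Fgl2 (-1.03 ± 0.16) and Apoe (-0.86 ± 0.13), while resident fibroblast (1 and 8 adjusted over the list alone, fry adjusted p = 0.00419), complement (0 and 3 adjusted over the list alone, fry adjusted p = 0.00745) and basement membrane genes (0 and 3 adjusted over the list alone, fry adjusted p = 0.0345, adjusted p = 0.163 with an estimated correlation) differed downward as lists. There 703 genes had an unadjusted p under 0.05. DESeq2 called 15, limma-voom 7 and edgeR with no filter 23.

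Cultured aged and young cells were compared over the 4 substrates to ask what cell age changes once the surroundings are matched. Immediate early genes were lower in aged cells: 20 of 22 fell and 0 rose, with a median of -1.46 (0 and 20 adjusted over the list alone, fry adjusted p = 3.62e-17). Nr4a1, a nuclear receptor gene (ENSMUSG00000023034, chromosome 15, 101152150 to 101172677), measured 252 ± 7.68 CPM in young and 13.6 ± 5.15 CPM in aged cells on StiffY (-4.79 ± 0.10, adjusted p = 7.95e-22), and Egr1 and Fos changed by -2.73 ± 0.09 and -2.58 ± 0.14. 14 of 24 cytokines and NF-kB targets fell and 3 rose, with Ccl2 at -1.25 ± 0.04 (3 and 14 adjusted over the list alone, fry adjusted p = 1.78e-06). Myeloid markers fell in 2 of 5 cases, with Cd68 at -1.10 ± 0.27 (0 and 2 adjusted over the list alone, fry adjusted p = 0.0218, adjusted p = 0.574 with an estimated correlation). YAP and TAZ targets fell in 7 of 19 cases with 1 higher, with Ccn1 at -0.96 ± 0.04 (2 and 8 adjusted over the list alone, fry adjusted p = 8.54e-08). Contractile genes fell in 8 of 16 cases, with Acta2 at -0.33 ± 0.06 (1 and 9 adjusted over the list alone, fry adjusted p = 2.17e-06). TGF-beta response genes fell in 7 of 19 cases with 1 higher, led by Junb (-1.58 ± 0.06), which is also an immediate early gene (2 and 7 adjusted over the list alone, fry adjusted p = 1.99e-09). The fibrillar collagen list was split, with 8 of 25 higher, such as Tnc (0.70 ± 0.04), and 9 lower, such as Eln (-2.19 ± 0.08) and Col1a1 (-0.26 ± 0.03). Its median and mean were positive and its test pointed downward (10 and 9 adjusted over the list alone, fry adjusted p = 0.00340, adjusted p = 0.463 with an estimated correlation). Timp3 rose by 0.90 ± 0.05, the arrest gene Cdkn2a by 1.21 ± 0.23 and the class II gene H2-Ab1 by 2.19 ± 0.24. 11 of 24 unfolded protein response genes rose and 1 fell, with Hsp90b1 at 0.42 ± 0.04 (13 and 2 adjusted over the list alone, fry adjusted p = 4.43e-05, adjusted p = 0.0867 with an estimated correlation).

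Endothelial markers moved with cell age: 8 of 13 rose, with Cdh5 at 1.41 ± 0.13, and 2 fell, with Ptprb at -0.91 ± 0.09 (9 and 3 adjusted over the list alone, fry adjusted p = 4.51e-06). The cardiomyocyte marker Tnnt2 changed by -1.63 ± 0.18 (0 and 1 adjusted over the list alone, fry adjusted p = 2.17e-06). Schwann cell markers rose in 2 of 3 cases, with Prnp at 0.47 ± 0.08 (2 and 1 adjusted over the list alone, fry adjusted p = 2.41e-04, adjusted p = 0.147 with an estimated correlation). Libraries also differed within groups along 1 axis that took 31.2% of the within-group variance over 7358 genes. Of the 100 genes at its high end, 59 fell and 0 rose in aged cells, with a median of -0.73. Among all 12841 genes, 837 rose and 1091 fell. With counts summed per library number, in case 1 number is 1 cell preparation, 635 genes passed, and 614 of them were among the 1928.

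The genes that differed by age in fresh cells were followed in culture to ask whether a substrate or culture comparison moves them the same way. Of 14 fry tests, 2 were called: genes higher in fresh aged cells were higher with aged ECM in aged cells (adjusted p = 0.0474), and genes lower in fresh aged cells were lower in cultured aged cells (adjusted p = 0.0474). Both had an adjusted p = 0.408 with an estimated correlation. With the 200 genes of smallest p in each direction, 7 were called, 3 along fresh ageing and 4 against it. Along it, genes lower in fresh aged cells were lower with aged ECM in young cells (adjusted p = 1.06e-06), in cultured aged cells (adjusted p = 8.69e-07) and, with a positive median, on StiffA in young cells (adjusted p = 0.0172, adjusted p = 0.290 with an estimated correlation). Against it, these genes were higher with stiffness in young (adjusted p = 1.88e-04) and aged cells (adjusted p = 2.63e-04) and on StiffA in aged cells (adjusted p = 0.00148, adjusted p = 0.0523 with an estimated correlation). Genes higher in fresh aged cells were lower in cultured aged cells (adjusted p = 3.26e-05, adjusted p = 0.0532 with an estimated correlation). The higher genes with aged ECM in aged cells were not called with the 180 measured top genes (adjusted p = 0.119), at a median of 0.08 against 0.09 for all 1627. 223 genes were higher in both fresh and cultured aged cells (105 if independent), 259 lower in both (171) and 323 opposite (268). Across 11379 genes, which are not independent replicates, the correlation of log2 folds with those of fresh ageing was 0.14 for aged ECM in both young and aged cells. It was 0.14 for cultured age, and 0.12 and 0.07 for StiffA over SoftY in young and aged cells. For stiffness it was 0.04 in young and -0.08 in aged cells.

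**Figure D5:**
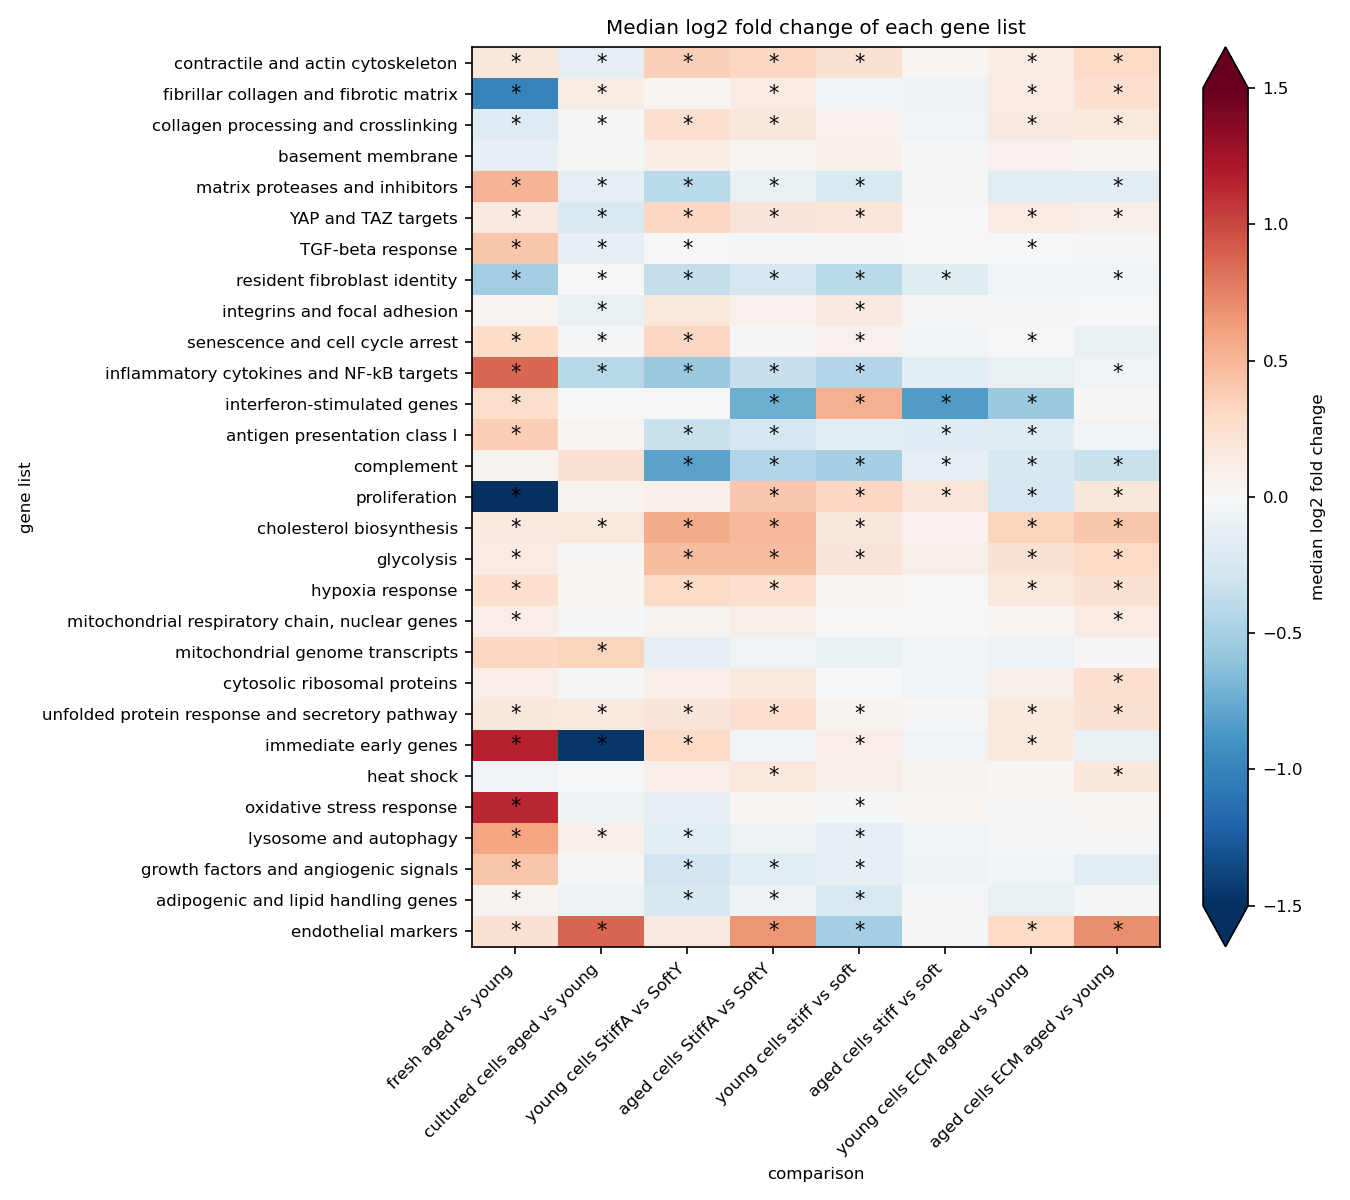
Median log2 fold change of 29 gene lists with at least 10 measured members in 8 comparisons, on a colour scale that ends at 1.5 in both directions. A star marks a list with a fry adjusted p under 0.05. Proliferation is lowest in fresh aged cells, and immediate early genes are high in fresh aged and low in cultured aged cells.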

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

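Of the tests here, those of myeloid markers, of differences between library letters and of single groups, both of the immediate early genes, that of GC content, that of animals and the splits of fresh cells and of aged StiffA against SoftY were chosen only after the result was seen. The axis score was itself taken as a covariate only after the data were seen, which holds for its test on the interferon-stimulated list too. An interaction test of the difference picked out the genes and counts in the next 2 paragraphs.

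Stiffness acted differently by cell age on 101 genes and on the interferon-stimulated list as a whole (median -1.39). The values, aged minus young, were Saa3 2.02, Col15a1 1.88, Pecam1 1.75, Enpp2 1.51, Adhfe1 1.37, Il33 1.28, Steap4 1.04, Atp1b2 1.01, Cmpk2 -3.36, Ifit1 -3.17, Ifit3b -2.68, Isg15 -2.41, Usp18 -2.20, Ifit3 -2.18, Ifi44 -2.00 and Oas1a -1.90. Aged ECM acted differently by age on 12 genes, among them Oas1a 1.15, Ccn4 0.77, Tpx2 0.67, Cnmd -1.39, Enpp2 -1.09, Fgl2 -1.06, Sfrp2 -0.70, Apoe -0.69, Gsn -0.46 and Fbln1 -0.43.

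Stiffness acted differently on aged and young ECM for 79 genes in young cells. The values were Enpp2 4.96, Col15a1 3.76, Cnmd 3.28, Steap4 2.33, Atp1b2 2.15, Sparcl1 2.02, Serpina3f 1.97, Anpep 1.75, Arpin -1.22, Tcf21 -1.15, Top2a -1.03, S100a10 -1.01, Prss23 -0.88, Scel -0.85, Mid1ip1 -0.82 and Tm4sf1 -0.80. In aged cells it did so for 3 genes, Htra3 -1.31, Fgl2 -1.03 and Apoe -0.86.

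Interferon-stimulated genes were higher on stiff substrates in young cells and lower in aged cells. With the axis score as a covariate the list's median in the interaction was -1.41, which argues against the axis as the whole cause. Young cells had library numbers 1 to 3 and aged cells 4 to 6, and set against each other in that order the differences were -1.37, -1.57 and -1.34, which argues against 1 library number alone. Number 2 had soft and stiff libraries on aged ECM only, and with number 5 on that ECM alone its difference was -1.38. The change of number 4 on young ECM was small (-0.11). Myeloid markers had a median of the other sign (0.759), which leans against a change in the number of myeloid cells. This is weak, since no marker passed over all genes and the list's call was lost with an estimated correlation. The letter in the library names marks the substrate and is shared by both ages, so that a shift of a letter adds equally to both. Such a shift alone leaves no difference between ages, and the one that raised the question was present on each ECM (aged minus young in stiff minus soft of the list mean -1.01 ± 0.20 (SE) on young and -1.75 ± 0.19 on aged ECM), which argues against letters as the whole cause. Culture differences of single groups, each 1 age on 1 substrate, cannot be told apart from the groups, and the largest SD of the list within a group was 0.213. An effect of cell age on the interferon response to stiffness stays open as a hypothesis.

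Immediate early genes were higher in fresh aged cells and lower in cultured aged cells. With the axis score as a covariate their median in cultured cells was -1.42, which argues against the axis as the whole cause. Handling at isolation or harvest cannot be told apart from cell age, since these genes answer handling quickly and heat shock genes, the only handling readout tested, had a median of 0.00846 in cultured cells with members on both sides of 0. An effect of cell age was not tested apart from handling.

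Libraries numbered 1, 3 and 5 in their names deviated from their group means along 1 axis in 1 direction per number, and those numbered 2, 4 and 6 in both directions. Gene loadings on it correlated with the highest GC content of any 100-base stretch (Spearman 0.359), the largest of the properties computed. The values were 0.277 for GC of the first 300 bases, 0.183 for length, 0.022 for GC of the whole transcript and -0.050 for its last 300 bases. Loss or gain of transcripts with a GC-rich stretch in library preparation is thus a candidate cause. It was not tested apart from GC at the transcript start or from length. Depth stays open, since the Pearson correlation of the axis with total counts (0.209, permutation p = 0.275) lay between the bounds of under 0.2 and 0.5 or more set against and for it. The Spearman correlation (0.116, p = 0.547) was under the lower bound, which leans against depth. Animals (lowest correlation of young libraries that share a number -0.137) cannot be told apart from library numbers, since the labels tie no number to an animal. The high-end genes of this axis had medians of -0.78 for StiffA over SoftY in aged cells, -0.76 with aged ECM in aged cells, -0.73 with cell age and -0.53 in the interaction of age with ECM. In the interaction of stiffness with ECM in young cells their median was 0.39, and that of the low-end genes -0.54. In the same interaction in aged cells the low-end median was -0.35. In fresh aged cells 42 of 99 low-end genes rose and 10 fell (median 0.32).

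Random splits of the same libraries asked whether a chance division calls as many genes. For fresh age (3750 genes, 0 in the highest other split) and aged StiffA over SoftY (541, 0) only 10 splits exist, too few for a share under 0.05, and the real split alone, 1 of 10, reached its count in each. For the other results 100 splits were counted, the real one included. The real split alone reached its count for cultured age (1928 against 122 in the highest other split, reached in 1 split). So it did for aged ECM in aged cells (956, 412, 1) and stiffness in aged cells (38, 1, 1). In a model of 2 groups the same held for cultured over fresh young (6736, 0, 1) and aged cells (7925, 0, 1). This argues against chance if single libraries can be exchanged freely. If 1 library number is 1 preparation, cultured age has too few units for a share under 0.05, as in fresh cells. Chance was not excluded for cultured age in that case. The share was also under 0.05 for stiffness in young cells (457, 776, 3) and aged ECM in young cells (320, 375, 2). It was likewise for the interactions of age with stiffness (101, 327, 3) and with ECM (12, 763, 4). The interactions of stiffness with ECM in young (79, 174, 4) and aged cells (3, 652, 3) had such a share too. For all of these, 1 to 3 other splits called as many genes or more, so that counts of this size did arise by chance. The splits for interactions also shuffled the effects of single cues, which widens the spread within groups. They cannot decide on an interaction alone. Some splits called several times the real count, as with 763, 652 and 327 genes. A structure of the samples beyond the groups may be behind this, which was not tested. With such structure the libraries are not freely exchangeable, and a low share does not exclude chance. Young StiffA over SoftY, with 2 libraries on SoftY, was not split.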

How the results depend on the processing

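The tests with the axis covariate, without 2 young libraries and with counts summed per library number were chosen only after the result was seen. Named genes were refitted under the alternatives in 22675 cases: 21796 kept their direction and call, 879 kept the direction and lost the call, and 0 reversed. Most cases left out a single library. Of the 1119 named results with a call, 213 lost it under at least 1 alternative. With counts summed per library number, 42 cases of cultured age lost it, while 93, with or without a call, stayed the same. These genes were picked by fold or p in the main fits, so that stability is partly built in. Of 3417 cases of named genes without a call, 3363 stayed without one, 54 gained one and 0 reversed. The p-values measure the spread between libraries, groups of 2 or 3 leave small effects unseen, and where 1 library of young cells on SoftY was left out the other was assumed to vary like the other groups. Library numbers are shared between groups in the labels without a meaning. Pairs of libraries with the same title number had correlations of deviations of -0.46 to 0.65 in young cells (18 of 26 over 0.1) and -0.09 to 0.48 in aged cells (24 of 30), and 7 of 14 and 13 of 15 libraries correlated best with their own number. By the number in the library name 21 of 26 young pairs were over 0.1 and 10 of 14 libraries correlated best with it. Pairs that shared that number deviated together on average (mean 0.260 in young and 0.163 in aged cells, against -0.129 and -0.0801 for other pairs), which hints at a shared origin. No label gives the number a meaning, and the numbers were not taken to pair the samples. That some pairs fell below 0.1 does not argue against a shared origin. The reported p-values take the libraries as independent. If 1 number is 1 preparation, those of cultured age are too small, and fewer genes passed there with counts summed per number.

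Counts of genes moved by more than 1.5 times as follows. With no filter the interactions gave 186 (young, stiffness by ECM), 23 (aged) and 111 (age by ECM), and with DESeq2 152, 15 and 33. Limma-voom with sample weights gave 1099 for aged cells StiffA vs SoftY, 1655 for aged cells ECM aged vs young, and 152, 7 and 33 for those interactions. With the replicate block by title, aged cells StiffA vs SoftY gave 861, aged cells ECM aged vs young 1492, the aged interaction 5 and age by ECM 70. With the replicate block by library number they gave 977, 1630, 5 and 31, and the young interaction 267. All libraries in 1 fit gave 145 for the young interaction and 19 for age by ECM. Without 2 young libraries age by ECM gave 111. With the axis covariate, young StiffA over SoftY gave 1086, stiffness in young cells 813, aged ECM in young cells 558, stiffness in aged cells 64, and the interactions 194 (young), 10 (aged), 186 (age by stiffness) and 41 (age by ECM). The axis was drawn from the spread within groups of these libraries, so that as a covariate it lowers that spread by construction. Higher counts with it are thus partly built in, and their p-values may be too small. Counts summed per library number gave 635 for cultured age. Over 10 comparisons fry called 234 lists, and camera with an estimated correlation called 117, counted separately. For genes of fresh ageing, fry called 2 tests, camera with a preset correlation 7, with an estimated one 0, and fry on the 200 top genes 7. RLE factors moved no count of genes by more than 1.5 times.

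With each library left out in turn, counts ranged from 3035 to 4001 for fresh age, 335 to 529 for young and 280 to 516 for aged StiffA over SoftY, 304 to 555 for stiffness in young and 26 to 38 in aged cells, 179 to 346 for aged ECM in young and 596 to 1088 in aged cells. They ranged from 47 to 211 for the young and 3 to 3 for the aged interaction, 1305 to 2550 for cultured age, 72 to 137 for age by stiffness, 3 to 33 for age by ECM, and 6783 to 7765 and 7504 to 8407 for cultured over fresh young and aged cells.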

Other observations

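No tests in this part were chosen only after the result was seen. Growth factor and angiogenic genes rose in fresh aged cells in 11 of 23 cases, and 2 fell (12 and 2 adjusted over the list alone, fry adjusted p = 0.00145, adjusted p = 0.153 with an estimated correlation), while with stiffness in young cells 5 of 25 fell and 1 rose (1 and 6 adjusted over the list alone, fry adjusted p = 3.92e-04). The hypoxia response list rose with aged ECM in aged cells, with 3 of 13 members higher (4 and 0 adjusted over the list alone, fry adjusted p = 1.01e-05), and 5 of 13 rose in fresh aged cells (5 and 2 adjusted over the list alone, fry adjusted p = 0.00115, adjusted p = 0.282 with an estimated correlation). Chondro-osteogenic genes fell with stiffness in young cells in 3 of 11 cases, and 1 rose (1 and 6 adjusted over the list alone, fry adjusted p = 5.22e-06). Adipogenic genes fell in 4 of 15 cases there, and 1 rose (1 and 5 adjusted over the list alone, fry adjusted p = 2.84e-04). Basement membrane genes rose with culture in 15 of 18 cases in young cells and 1 fell (15 and 1 adjusted over the list alone, fry adjusted p = 4.23e-17). Integrin genes fell in 6 of 23 cases in cultured aged cells, and 2 rose (2 and 9 adjusted over the list alone, fry adjusted p = 2.83e-05, adjusted p = 0.0867 with an estimated correlation).

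Ribosomal protein genes fell with culture in 37 of 38 cases in young cells (0 and 37 adjusted over the list alone, fry adjusted p = 7.93e-10, adjusted p = 0.126 with an estimated correlation) and in 38 of 38 in aged cells (0 and 38 adjusted over the list alone, fry adjusted p = 2.15e-11, adjusted p = 0.136 with an estimated correlation). Nuclear respiratory chain genes fell in 21 of 33 cases in aged cells with culture, and 2 rose (2 and 21 adjusted over the list alone, fry adjusted p = 5.94e-09, adjusted p = 0.373 with an estimated correlation). Transcripts of the mitochondrial genome rose in cultured aged cells in 5 of 11 cases (7 and 0 adjusted over the list alone, fry adjusted p = 0.00549, adjusted p = 0.304 with an estimated correlation). Heat shock genes had 4 of 11 higher and 3 lower in fresh aged cells and were not called as a list (4 and 3 adjusted over the list alone, fry adjusted p = 0.387, with its median below 0 and its mean above). Genes at 0 in 1 group included Col28a1, with 0 counts in fresh aged cells and at least 887-fold higher in culture, and Sprr2h, at least 468-fold lower in cultured aged than in fresh aged cells.

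Among markers of other cells, pericyte and smooth muscle markers fell in 3 of 5 cases in fresh aged cells, and 1 rose (1 and 3 adjusted over the list alone, fry adjusted p = 0.00108, adjusted p = 0.153 with an estimated correlation). Schwann cell markers rose in 2 of 3 cases (2 and 0 adjusted over the list alone, fry adjusted p = 6.21e-04, adjusted p = 0.371 with an estimated correlation). The cardiomyocyte list held 1 measured gene in fresh cells, Myl4, which did not pass over all genes (0 and 1 adjusted over the list alone, fry adjusted p = 0.0304, adjusted p = 0.639 with an estimated correlation). The lymphocyte list held 1, which rose (1 and 0 adjusted over the list alone, fry adjusted p = 0.0515). Of sex-linked transcripts Xist alone was measured and passed no test in fresh aged cells (0 and 0 adjusted over the list alone, fry adjusted p = 0.146). Of the erythroid list, 0 genes passed the filter. A changed marker does not count cells.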
